A study of Mus musculus with 8 samples.

How the data were processed

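Total RNA from frozen dorsal skin of Balb/c mice was measured on 8 Affymetrix Mouse Genome arrays, 1 per sample, after amplification from the 3' end and biotin labelling, per the labels' protocols. The labels name the smaller 430A array, whereas the table held 45101 probe sets and the probe annotation used here was that of the larger array of the same generation. The values were log2 signals per probe set as deposited by the authors, and the log2 scale was read from their range. The submitters' processing notes name Affymetrix Expression Console and MAS5, without a version or an order of steps. The trimmed mean of the linear signals, leaving out 2% at each end, ran from 43.4 to 58.8 between arrays, so the deposited values were not scaled to a single common target, and how the authors normalized between arrays is not given in the sources used here. No detection calls were analysed here. A fold against a group whose signal lies near the array median, which was 4.07 to 4.21 on the log2 scale, is therefore approximate.

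Samples were grouped by the labels into sham (n = 2), DNCB (n = 3) and DNCB+HY209 (n = 3). Sham was read from titles and source names, because the growth and treatment protocol fields of these samples carry the same text as those of the DNCB group. The labels do not state that the arrays of a group came from separate animals, so p-values measure the spread between these samples, which are taken as independent. Of the probe sets, 64 were controls, 34945 were paired with 1 gene symbol, 932 with several and 9160 were not listed in the probe annotation. Symbols were checked through their Entrez identifiers, of which 99.4% matched, and 0 symbols needed an update. Control probe sets were left out of the tests. A probe set was kept if its signal lay above the median of its array on at least 2 of the 8 arrays, which left 24675, and a gene was represented by its probe set with the highest mean, which gave 12420 genes. The values were used as deposited, with no pseudocount because they were already on a log2 scale.

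Differences between groups were tested with limma (version 3.58.1 in R 4.3.3), with lmFit and eBayes with an intensity trend, in a single fit of all 8 arrays, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Adjusted p-values of single genes are from this test. SE is the moderated standard error of a log2 difference. Fixed gene lists, 36 in number, were tested with camera at a preset correlation between genes of 0.01 where at least 5 members were measured, which held for 30 lists, with adjustment over lists and the 3 comparisons together. For each list the same test with an estimated correlation and the rotation test fry were also run. The lists, the groups, the tests and all alternatives, except those named as added, were set before the data were examined.

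Genes were named by a rule. For each comparison these were the 5 largest increases and 5 largest decreases past the threshold with no overlap between the arrays of the groups, or, where none passed, the 3 highest and 3 lowest by moderated t among genes with no overlap, given as values. Added to these were up to 3 members of each passing list in order of its camera p, and a fixed set of genes (Il4, Il13, Tslp, Il33, Il1b, Tnf, Nlrp3, P2rx7, Gpbar1, Flg, Lor, Krt6a, Ccl17, S100a8 and Cd4). At most 30 genes were taken per comparison. Further genes are named where stated.

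The alternatives were quantile normalization, centring each array on its median, no filter, a stricter filter, all probe sets, the mean of a gene's probe sets, no intensity trend, a robust variance, array weights, a fit of only the groups compared, the replicate number as a block, each array left out in turn and a test against a 1.5-fold change. Covariates for the spike-in level, the Gapdh 3' to 5' difference and the levels of the hair follicle and skeletal muscle lists, and a fit without a pair of arrays of extreme spike-in level, were added after the data were examined. Shares and fractions that set the groups against a shared control were compared with 100 simulated data sets that kept the covariance of the arrays' deviations and had no HY209 effect. The test was also run on simulated data with known changes in the 12420 genes. In these data each gene varied on its own, without the variation between arrays that real genes share. The rates of recovery need not hold for the real arrays. For DNCB against sham the test recovered 18.3% of genes changed by 1 log2 unit and 94.4% of those changed by 2. For DNCB+HY209 against DNCB it recovered 37.5% and 92.3%, and for DNCB+HY209 against sham 16.7% and 90.4%. The number of arrays limits the precision of all values. Figures were drawn with Python 3.11.15.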

Results

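Gene expression was profiled in dorsal skin of mice in a model of atopic dermatitis. The hapten 1-chloro-2,4-dinitrobenzene (DNCB), a contact sensitizer, was applied for 15 days, and over the last 7 days the skin received either vehicle or a gel with 5% HY209, described as an agonist of the bile acid receptor GPCR19. Sham samples were those whose titles and source names give no DNCB and no HY209, although their protocol fields carry the text of the DNCB model, a doubt that bears on each comparison against sham. The 8 arrays comprised 2 sham, 3 DNCB and 3 DNCB+HY209 samples. Signals of different arrays correlated across probe sets with r of 0.965 to 0.986 within groups and 0.920 to 0.987 between groups, and no array was a duplicate of another.

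The arrays differed in quality measures. The mean log2 signal of the 7 bacterial spike-in probe sets was 11.68 ± 0.47 (SD, n = 2) in sham, 10.65 ± 0.86 (n = 3) in DNCB and 10.64 ± 0.54 (n = 3) in DNCB+HY209. The ratio of 3' to 5' Gapdh signal, which rises with RNA degradation, ran from 2.10 to 7.35, with the highest value on DNCB array 3. The first principal component held 56.8% of the variance and correlated with the spike-in signal over the 8 arrays (Pearson r = -0.934, exact permutation p = 0.000347, adjusted p = 0.00104, and Spearman rho = -1 with exact permutation p = 4.96e-05, adjusted p = 0.000149, for 3 such relations). Within groups r was -0.928, and without DNCB array 2 and sham array 2, the farthest in spike-in signal, it was -0.865. The component also correlated with the SD of the log2 values (r = 0.915, exact permutation p = 0.00156, adjusted p = 0.00234; rho = 0.929, exact permutation p = 0.00223, adjusted p = 0.00335; r = 0.939 within groups and 0.816 without DNCB array 2 and DNCB+HY209 array 3). With the log2 Gapdh ratio r was -0.488 (exact permutation p = 0.221, adjusted p = 0.221) and rho was -0.786 (exact permutation p = 0.0279, adjusted p = 0.0279). That r was -0.690 within groups and -0.770 without DNCB array 3 and sham array 1.

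**Figure D1:**
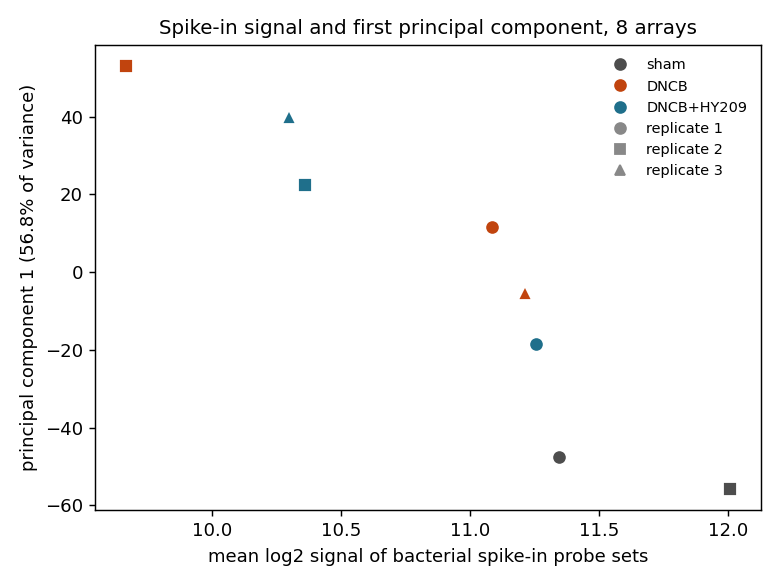
First principal component of the 8 arrays (vertical axis, 56.8% of the variance) against the mean log2 signal of the bacterial spike-in probe sets (horizontal axis), with 1 point per array, coloured by group and shaped by replicate number. Arrays with less spike-in signal lie higher on the component (Pearson r = -0.934).

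The first comparison asked what DNCB changed in the skin. Genes of activated keratinocytes were among the largest increases. Krt6b, a keratin of wounded and hyperproliferative epidermis, rose from a log2 signal of 5.06 ± 1.31 (SD, n = 2) in sham to 13.76 ± 0.31 (n = 3) in DNCB, a log2 difference of 8.70 (SE 0.55, adjusted p = 0.000431). Its partner keratin Krt16 rose by 7.65 (SE 0.52, adjusted p = 0.000431) and the envelope precursor Sprr1b by 7.04 (SE 0.83, adjusted p = 0.0109). Krt6a, another keratin of this type, rose by 3.73 (SE 0.63, adjusted p = 0.0295). The sham signal of Sprr1b, 3.67, lay below the array medians, where log2 differences are approximate. Of the 29 measured hyperproliferative and alarm keratinocyte genes, 8 rose, 0 fell and 21 did not pass (18 rose and 1 fell when adjusted over the list alone). The list stood above the other genes (camera adjusted p = 2.64e-10, adjusted p = 0.686 with an estimated correlation). For this comparison camera passed 13 of 30 lists at the preset correlation, 0 with an estimated correlation and 0 with fry. In simulated data with nothing shifted, run for DNCB+HY209 against DNCB only, the preset test passed a median of 11.5 lists. Their p-values were adjusted over the lists of that comparison alone, unlike the real ones, so the counts are not like-for-like. A camera call at the preset correlation alone therefore does not show that a list shifted.

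Of the inflammatory lists, the neutrophil list and both interferon lists were higher at the preset correlation, and others did not pass. Stfa3, a cysteine protease inhibitor of the stefin family, rose by 6.25 (SE 0.43, adjusted p = 0.000431), and the calprotectin subunits S100a9 and S100a8, abundant in neutrophils and in stressed keratinocytes, rose by 6.01 (SE 0.78, adjusted p = 0.0147) and 5.73 (SE 0.70, adjusted p = 0.012). These 3 were the members of the neutrophil list that rose, of 14 measured (6 rose and 0 fell when adjusted over the list alone), and the list stood above the other genes (camera adjusted p = 0.0020, adjusted p = 0.686 with an estimated correlation). Of 21 type I interferon response genes 6 rose and 0 fell (17 rose when adjusted over the list alone), and the list stood above the other genes (camera adjusted p = 4.01e-11, adjusted p = 0.686 with an estimated correlation). Oasl2 rose by 3.43 (SE 0.34, adjusted p = 0.00494) from a sham signal of 2.64, below the array medians and identical on both sham arrays (SD 0). Rtp4 rose by 2.94 (SE 0.28, adjusted p = 0.00343) and Ifit1 by 2.87 (SE 0.45, adjusted p = 0.0234). Of 15 genes of the type 1 and interferon gamma response 6 rose and 0 fell (11 rose when adjusted over the list alone), with a camera adjusted p = 2.34e-07 (adjusted p = 0.686 with an estimated correlation). They included the chemokine Cxcl9, which rose by 3.09 (SE 0.50), and the interferon-induced GTPases Igtp and Gbp3, which rose by 2.13 (SE 0.39) and 1.93 (SE 0.35). The sham signals of S100a9 (3.80), Ifit1 (3.31) and Cxcl9 (4.01) also lay below the array medians. Lists that did not pass were the macrophage and monocyte markers (mean 0.62, camera adjusted p = 0.0541), the NF-kB and innate cytokine genes (mean 0.61, camera adjusted p = 0.0786), the T cell markers (mean -0.08, camera adjusted p = 0.193) and the type 17 list (mean -0.06, median 0.22 and camera direction lower, adjusted p = 0.305). Single members of 3 of them passed by limma, named after their values were seen. Of 19 macrophage markers Ms4a7 rose by 1.82 (SE 0.37; 3 rose when adjusted over the list alone), of 25 NF-kB genes the adhesion molecule Icam1 rose by 1.85 (SE 0.34; 5 over the list alone), and of 8 type 17 genes Il20ra fell by 1.33 (SE 0.26).

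Stromal and vascular lists stood above the other genes at the preset correlation only. The members named in this paragraph were chosen after their values were seen, because the counts are small. Of 15 endothelial and lymphatic markers 5 rose (10 when adjusted over the list alone), with a camera adjusted p = 1.15e-06 (adjusted p = 0.686 with an estimated correlation). They were the endothelial cadherin Cdh5 (2.20, SE 0.34), the lymphatic marker Pdpn (1.98, SE 0.38), Emcn (1.86, SE 0.36), Plvap (1.83, SE 0.36) and the tight junction gene Cldn5 (1.03, SE 0.21). The sham signal of Emcn, 3.12, lay below the array medians. Of 23 fibroblast and extracellular matrix genes 4 rose (8 when adjusted over the list alone), namely tenascin C (Tnc, from 4.94 to 8.95, SE of the difference 0.71), Pdgfrb (3.18, SE 0.50), Col5a1 (2.17, SE 0.39) and Col6a3 (2.13, SE 0.39). Each gene is represented by its brightest probe set, and the lowest difference among the probe sets was 1.22 for Pdgfrb and 0.47 for Col5a1. The camera adjusted p of this list was 0.00131 (adjusted p = 0.766 with an estimated correlation), and without sham array 1 it was 0.309. Of 15 matrix degradation and wound genes 1 rose, the metalloprotease gene Adam12 (1.74, SE 0.34; 5 rose when adjusted over the list alone; camera adjusted p = 0.00123, adjusted p = 0.766 with an estimated correlation).

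Further lists passed with few or no single genes past the threshold, and single arrays ended each of these calls. Oxidative phosphorylation, with 0 of 24 genes by limma, had a camera adjusted p = 0.0134 (adjusted p = 0.806 with an estimated correlation). It was 0.101 without sham array 2, 0.0744 without DNCB array 1 and 0.0791 without DNCB array 2. Cell cycle, with 0 of 30 genes, had a camera adjusted p = 0.0313 (adjusted p = 0.828 with an estimated correlation), and it was 0.596 without sham array 2, where the list turned lower, 0.0866 without DNCB array 2 and 0.219 without DNCB array 3. In the skeletal muscle list 1 of 25 genes rose, the myosin gene Myh2 (4.45, SE 0.48), named because it was alone (2 rose when adjusted over the list alone). Its camera adjusted p was 0.0496 (adjusted p = 0.828 with an estimated correlation), and 0.0800 and 0.0705 without DNCB+HY209 arrays 1 and 3. It turned lower by camera without sham array 1 (0.245) and without DNCB array 1 (0.942).

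Hair follicle genes were lower. The hair keratin-associated proteins Krtap19-3 fell by 5.37 (SE 1.05, adjusted p = 0.0437) and Krtap22-2 fell by 5.12 (SE 1.03, adjusted p = 0.0459). The predicted gene Gm10229 fell by 5.33 (SE 1.02) and Gm10228 fell by 5.20 (SE 0.94). Krt77, an epidermal keratin, fell by 5.27 (SE 0.79, adjusted p = 0.0219). Of 32 hair follicle genes 3 fell (8 when adjusted over the list alone), namely Krtap14, which fell by 4.56, Krtap6-2, which fell by 2.24, and Krtap3-1, which fell by 1.97. The DNCB signals of Krtap19-3 (2.98), Gm10228 (3.20), Krt77 (3.89), Krtap14 (3.12) and Krtap6-2 (3.61) lay below the array medians, where log2 differences are approximate. The hair follicle list lay below the other genes (camera adjusted p = 1.12e-15, adjusted p = 0.686 with an estimated correlation). The sham arrays differed from each other in this list, with mean log2 signals of 8.95 and 6.36, against 4.93, 5.04 and 6.64 in DNCB. The melanocyte list, with 0 of 10 genes past the threshold by limma, was also lower (camera adjusted p = 0.000121, adjusted p = 0.766 with an estimated correlation), with 0.128 without sham array 1. Its mean log2 signals were 7.64 and 5.65 in sham and 4.81, 5.18 and 6.20 in DNCB. The adipocyte list was lower with 0 of 12 genes past the threshold (3 fell and 1 rose when adjusted over the list alone; camera adjusted p = 0.0313, adjusted p = 0.766 with an estimated correlation), with 0.0885 without sham array 1 and 0.281 without DNCB array 3.

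Type 2 inflammation genes did not stand apart as a list (1 of 12 rose and 1 fell, 4 and 4 when adjusted over the list alone; camera adjusted p = 0.878). The interleukin 13 receptor gene Il13ra1 had a log2 difference of 2.43 (SE 0.49) and Retnla one of -1.30 (SE 0.25), both named because they were the members called, and the 4 probe sets of Il13ra1 ran from 1.09 to 2.43. The epithelial cytokines Tslp and Il33 had log2 differences of 2.48 (SE 0.68, adjusted p = 0.125) and 2.20 (SE 0.58, adjusted p = 0.114), and Il1b one of 1.37 (SE 0.34, adjusted p = 0.0952), with no overlap between the groups' arrays and no call. The barrier gene Flg differed by 3.88 (SE 1.25, adjusted p = 0.18) and Lor by 0.02 (SE 1.73, adjusted p = 0.996), and the probe sets of Lor disagreed in sign. After quantile normalization the difference of Lor was -0.18. Tnf, Nlrp3, P2rx7 and Cd4 differed by -0.33, -0.09, -0.50 and -0.31, with adjusted p of 0.384, 0.808, 0.393 and 0.41. The signals of Tnf (4.51 in sham and 4.18 in DNCB), Nlrp3 (4.07 and 3.99) and P2rx7 (4.40 and 3.89) lay near the array medians. Il4, Il13 and Ccl17 lay below the filter, and Gpbar1, which encodes GPCR19, had no probe set listed.

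In all, limma called 227 of 12420 genes, of which 170 rose and 57 fell in DNCB, and the median log2 difference of all genes was 0.15. Groups did not overlap for 34.4% of genes, against 20% by chance. Among the genes named by the rule, Krt6b, Krt16, Stfa3 and Rtp4 kept their call without each array in turn, and the calls of the others ended without at least 1 array. The count was 40 without sham array 1, 15 without sham array 2, 31 without DNCB array 1, 30 without DNCB array 2, 66 without DNCB+HY209 array 2 and 352 without DNCB+HY209 array 1. With the spike-in level as a covariate, added after the data were examined, it was 16, and without the pair of arrays of extreme spike-in level, DNCB array 2 and sham array 2, it was 7. With other covariates added in the same way it was 452 for the Gapdh ratio, 27 for the hair follicle level and 32 for the skeletal muscle level. With the replicate number as a block it was 35, and against a change of 1.5-fold, a stricter hypothesis, it was 25.

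**Figure D2:**
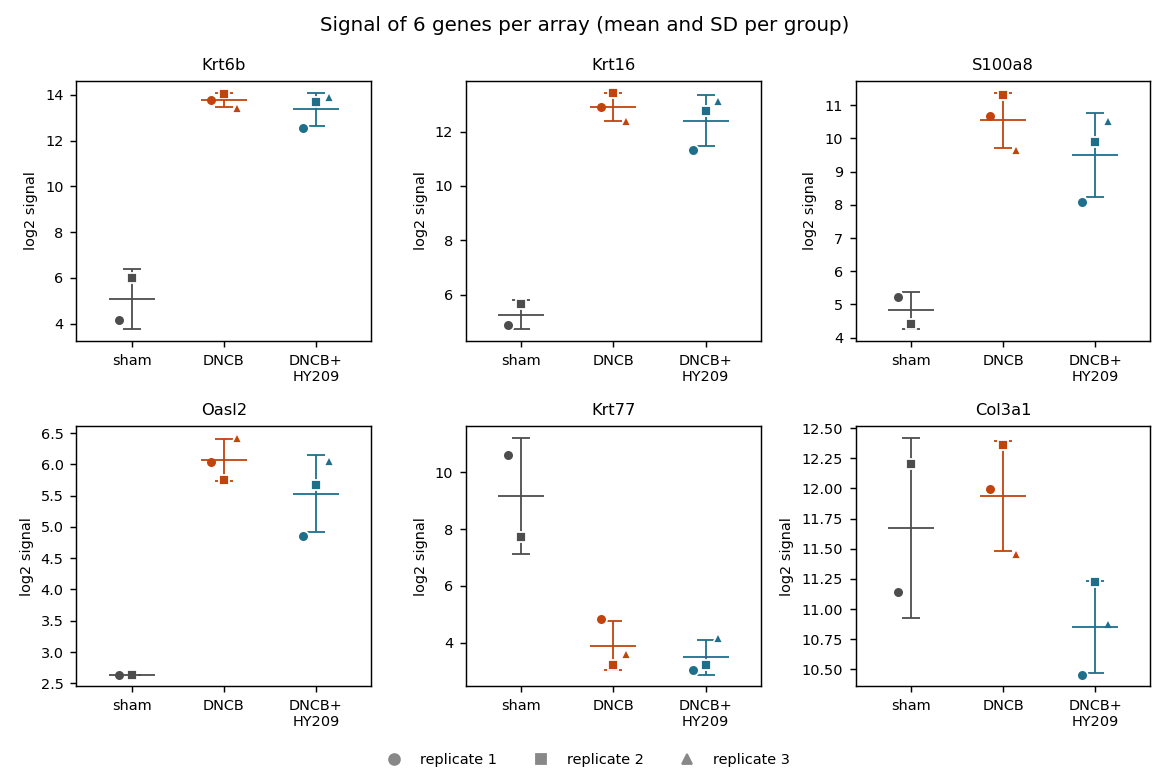
Log2 signal (vertical axes) of 6 genes on each of the 8 arrays, with points for arrays, shaped by replicate number, and bars for the mean and SD of each group (sham n = 2, DNCB n = 3, DNCB+HY209 n = 3). Krt6b lay at 5.06 in sham and at 13.76 in DNCB, while Krt77 lay at 9.16 in sham and at 3.89 in DNCB.

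The second comparison asked what HY209 gel changed in DNCB-treated skin. Limma called 0 of 12420 genes, with 161 at an unadjusted p under 0.05 (31 higher and 130 lower). Extracellular matrix and vascular lists lay lower with HY209 under the preset correlation. The 23 fibroblast and matrix genes had a mean log2 difference of -0.82, with 0 past the threshold (camera adjusted p = 1.51e-26, adjusted p = 0.64 with an estimated correlation). Among them the fibrillar collagens Col3a1 and Col5a2 differed by -1.08 (SE 0.34) and -1.14 (SE 0.38), with no overlap between groups. The 15 endothelial and lymphatic markers had a mean of -0.56 (camera adjusted p = 1.12e-14, adjusted p = 0.64 with an estimated correlation). Cdh5 had a log2 signal of 6.22 ± 0.37 (SD, n = 3) against 7.22 ± 0.54 (n = 3) and Emcn a difference of -0.88 (SE 0.32). The DNCB+HY209 signal of Emcn, 4.10, lay near the array medians, where log2 differences are approximate. The 15 matrix degradation genes had a mean of -0.57 (camera adjusted p = 2.64e-10, adjusted p = 0.686 with an estimated correlation), with -0.99 (SE 0.31) for Adam12 and -0.64 (SE 0.20) for Plat, whose second probe set differed by -0.010. DNCB array 3 had the highest Gapdh ratio (7.35), against 2.79 and 2.10 on DNCB arrays 1 and 2 and 3.24, 2.62 and 2.31 on the HY209 arrays. By that ratio the HY209 arrays were unlike DNCB array 3 and near the other DNCB arrays. In these lists, however, DNCB array 3 lay near the HY209 arrays. Its mean log2 signal was 7.53 for fibroblast and matrix genes, against 8.35 and 8.67 on the other DNCB arrays and 7.11, 7.46 and 7.52 with HY209. For endothelial genes it was 5.55, against 6.24 and 6.35 and against 5.22, 5.60 and 5.64, and for matrix degradation genes 6.13, against 6.45 and 7.52 and against 5.63, 6.47 and 6.29.

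Inflammatory lists lay lower too, with 0 members past the threshold by limma in each. The mean of 19 macrophage and monocyte markers was -0.39 (camera adjusted p = 3.54e-08, adjusted p = 0.686 with an estimated correlation), with -0.76 (SE 0.28) for the complement component C1qb and -0.75 (SE 0.33) for Ms4a7. The mean of 14 neutrophil markers was -0.48 (camera adjusted p = 2.34e-07, adjusted p = 0.64 with an estimated correlation), with -1.06 (SE 0.37) for the formyl peptide receptor Fpr2 and -0.44 (SE 0.20) for the histidine decarboxylase Hdc. The DNCB+HY209 signal of Hdc, 4.16, lay near the array medians. The mean of 21 type I interferon genes was -0.26 (camera adjusted p = 3.88e-06, adjusted p = 0.686 with an estimated correlation; 0.0840 without DNCB array 3), with -0.74 (SE 0.40) for Ifit1 and -0.63 (SE 0.35) for Mx1. The mean of 25 NF-kB and innate cytokine genes was -0.22 (camera adjusted p = 0.0020, adjusted p = 0.686 with an estimated correlation), and the p was 0.105 without DNCB array 2 and 0.350 without DNCB+HY209 array 1. The cytokine transcript Il1b differed by -0.79 (SE 0.30). The Gapdh ratio of DNCB array 3 (7.35) exceeded those of the HY209 arrays. Its mean log2 signal lay within the range of the HY209 arrays in 3 of these lists. For macrophage genes it was 5.41, against 6.03 and 6.30 on the other DNCB arrays and 5.58, 5.22 and 5.80 with HY209. For neutrophil genes it was 6.01, against 6.44 and 6.84 and against 5.49 to 6.36 with HY209, and for NF-kB genes 5.55, against 5.76 and 6.23 and against 5.19, 5.81 and 5.88. For type I interferon genes it was 6.30, above the 5.61, 5.93 and 6.15 with HY209, and DNCB array 2 (5.84) lay within that range.

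Keratinocyte and other lists also lay lower. The keratinocyte alarm list had a mean of -0.43 (camera adjusted p = 3.91e-06, adjusted p = 0.766 with an estimated correlation), with 0.171 without DNCB array 2 and 0.268 without DNCB+HY209 array 1. The cornified envelope list had a mean of -0.38 (camera adjusted p = 0.00201, adjusted p = 0.806 with an estimated correlation), with 0.415, 0.119, 0.959 and 0.357 without DNCB arrays 1 and 2 and DNCB+HY209 arrays 1 and 2. The complement list had a camera adjusted p = 0.0191 (adjusted p = 0.686 with an estimated correlation), with 0.183, 0.0812, 0.104 and 0.0806 without DNCB arrays 1 and 2 and DNCB+HY209 arrays 2 and 3. DNCB array 3 lay within the range of the HY209 arrays in these 3 lists, with means of 7.38 for alarm genes (8.21 and 9.07 on the other DNCB arrays), 7.40 for envelope genes (8.92 and 8.87) and 5.02 for complement (5.43 and 5.53). The HY209 arrays had means of 6.97, 7.86 and 8.54 for alarm genes, 7.04, 7.34 and 9.66 for envelope genes and 5.14, 4.99 and 5.16 for complement. Thus DNCB array 1 also lay within their range for alarm genes, and DNCB arrays 1 and 2 did so for envelope genes. The Schwann cell list had a camera adjusted p = 0.0448 (adjusted p = 0.686 with an estimated correlation), and it kept its call without DNCB array 2 or DNCB+HY209 array 1 but not without sham array 1 (0.0536), sham array 2 (0.0508), DNCB array 1 (0.562), DNCB array 3 (0.169), DNCB+HY209 array 2 (0.174) or DNCB+HY209 array 3 (0.143).

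Lists that lay higher with HY209 included the hair follicle list (mean 0.73, camera adjusted p = 2.41e-05, adjusted p = 0.773 with an estimated correlation) and the melanocyte list (mean 0.93, camera adjusted p = 3.38e-05, adjusted p = 0.766 with an estimated correlation). On DNCB+HY209 array 1 their mean log2 signals were 7.65 and 7.76, against 5.54 and 5.61 for hair and 5.50 and 5.72 for melanocyte genes on the other arrays of the group. Without that array the adjusted p was 0.202 for hair, with the direction turned, and 0.778 for melanocytes, and without DNCB array 2 it was 0.543 and 0.0791. Cell cycle genes had a mean of 0.28 (camera adjusted p = 5.76e-06, adjusted p = 0.766 with an estimated correlation; 0.0952 without DNCB array 1). Oxidative phosphorylation had a camera adjusted p = 0.012 (adjusted p = 0.806 with an estimated correlation), with 1.00 without DNCB array 3, 0.471 without DNCB+HY209 array 2 and 0.0806 without DNCB+HY209 array 3. The sebaceous list had a camera adjusted p = 0.0354 (adjusted p = 0.766 with an estimated correlation), with 0.966, 0.70 and 0.133 without DNCB array 2 and DNCB+HY209 arrays 1 and 3. The skeletal muscle list had a camera adjusted p = 0.0412 (adjusted p = 0.828 with an estimated correlation), with 0.119, 0.190 and 0.120 without DNCB array 2 and DNCB+HY209 arrays 1 and 2, and it turned lower without DNCB array 3 (0.0419).

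The type 1 and interferon gamma list did not stand apart (mean 0.0073, median -0.05 and camera direction lower, adjusted p = 0.841), nor did type 2 inflammation (mean -0.15, camera adjusted p = 0.19). Il33 differed by -1.22 (SE 0.52), S100a8 by -1.06 (SE 0.63), Krt6a by -0.51 (SE 0.56), Tslp by -0.50 (SE 0.60) and the barrier gene Flg by -0.23 (SE 1.12). Lor differed by -0.62 (SE 1.55), with probe sets of both signs, Tnf by -0.19 (SE 0.17), P2rx7 by 0.15 (SE 0.26), Nlrp3 by 0.24 (SE 0.16) and Cd4 by -0.076 (SE 0.17). Single arrays set several of these signs. Without DNCB+HY209 array 1 Krt6a differed by 0.038, Tslp by 0.18, Flg by 0.20 and P2rx7 by -0.036. Flg differed by 0.18, 0.15 and 0.23 without DNCB arrays 1 and 2 and DNCB+HY209 array 2, and Lor by 0.51 without the last of these. By moderated t the lowest of the genes without overlap were the transcription factor genes Mecom (-0.78, SE 0.18) and Ebf1 (-0.93, SE 0.23) and the endothelin gene Edn1 (-0.71, SE 0.16). The highest were the epidermal lipoxygenase gene Alox12e (0.98, SE 0.26), Edaradd (1.06, SE 0.32) and Pomt1 (0.48, SE 0.15), and the 4 probe sets of Edaradd ran from 0.061 to 1.06. The signals of Tnf (4.18 in DNCB and 3.99 with HY209), P2rx7 (3.89 and 4.04) and Nlrp3 (3.99 and 4.23) lay near the array medians. So did the DNCB signal of Pomt1 (4.17).

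The smallest adjusted p of a single gene was 1.00, and groups did not overlap for 4.99% of genes, against 10% by chance. Camera passed 17 of 30 lists at the preset correlation, 0 with an estimated correlation and 0 with fry, and it passed 10 without DNCB array 2 and 11 without DNCB+HY209 array 1. In simulated data with nothing shifted, camera at the preset correlation passed a median of 11.5 lists. The simulated p-values were adjusted over the lists of this comparison alone, unlike the real ones, so the counts are not like-for-like.

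**Figure D3:**
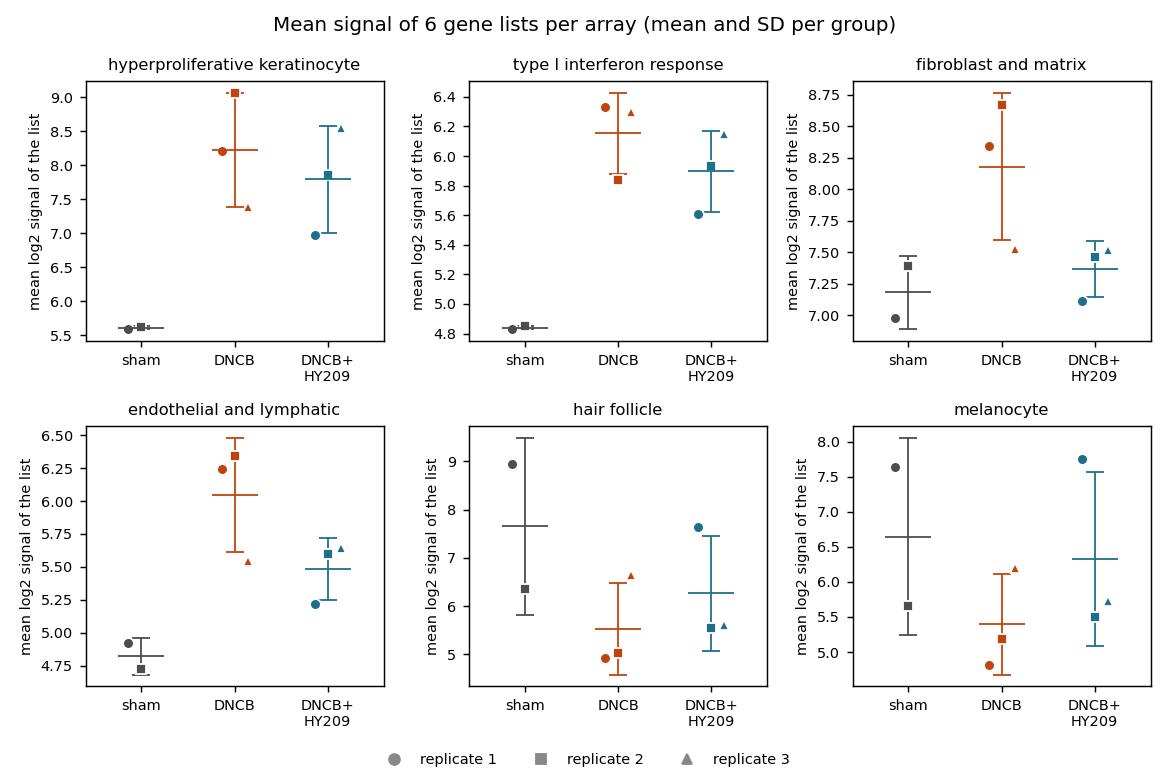
Mean log2 signal (vertical axes) of 6 gene lists on each of the 8 arrays, with points for arrays, shaped by replicate number, and bars for the mean and SD of each group (sham n = 2, DNCB n = 3, DNCB+HY209 n = 3). In the hair follicle list, sham array 1 lay at 8.95 and DNCB+HY209 array 1 at 7.65, each above the other arrays of its group.

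A further question was whether HY209 moved the DNCB-changed genes back towards sham. Of the 227 genes, 200 (88.1%) had the opposite sign under HY209, including 156 of the 170 raised genes and 44 of the 57 lowered ones, but the DNCB arrays enter both differences. In simulated data with no HY209 effect the median share was 61.8%, with 5% and 95% limits of 24.4% and 92.4%, and 14 of 100 simulations were as extreme. The simulations took the observed DNCB and sham means as true, so noise in those means counted as effect. They called a median of 787 genes in DNCB against sham (limits 16.9 and 6129), against 227 in the data. Their values are therefore not a like-for-like baseline. The median fraction of the DNCB difference that remained was 0.851, against 0.958 in simulations (limits 0.694 and 1.12, 23 of 100 as extreme). The share was 48.3% without DNCB+HY209 array 1, where 352 genes were called, and the remaining fraction was then 1.01. With genes chosen without DNCB array 1 or 3, and that array alone standing for DNCB, the share was 58.1% and 55.5%, and in the same way with DNCB array 2 it was 90%. Only 31 genes were called without DNCB array 1 and 30 without DNCB array 2, so these shares rest on other gene sets than the 227. Taken singly, the 3 HY209 arrays kept 0.627, 0.921 and 0.957 of the difference, and the 3 DNCB arrays had 0.985, 1.10 and 0.904. The DNCB arrays themselves define that difference and the choice of genes. Their values therefore lie around 1 by construction and are not a like-for-like baseline for the HY209 arrays.

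The last comparison set HY209-treated skin against sham. Among keratinocyte genes Krt6b rose by 8.30 (SE 0.55, adjusted p = 0.000664), Krt16 by 7.14 (SE 0.52, adjusted p = 0.000761) and Sprr1b by 6.49 (SE 0.83, adjusted p = 0.0203). The neutrophil list did not stand apart (mean 1.29, median 0.025, camera adjusted p = 0.299), and 3 of its 14 genes rose (4 when adjusted over the list alone), Stfa3 by 6.15 (SE 0.43, adjusted p = 0.000664), S100a8, and S100a9, named after its value of 4.84 (SE 0.78) was seen. S100a8 rose by 4.67 (SE 0.70, adjusted p = 0.0367), Oasl2 by 2.89 (SE 0.34, adjusted p = 0.0141) and Rtp4 by 2.71 (SE 0.28, adjusted p = 0.00678). The interferon-induced GTPase Iigp1 rose by 1.71 (SE 0.25, adjusted p = 0.033) and 2610528A11Rik by 4.99 (SE 0.80, adjusted p = 0.046). Krt77 fell by 5.68 (SE 0.79, adjusted p = 0.0294), and the cytochrome P450 gene Cyp2e1 fell by 4.22 (SE 0.66, adjusted p = 0.043). The semaphorin gene Sema3d fell by 3.34 (SE 0.22, adjusted p = 0.000664), the hair gene Krtap4-1 fell by 3.18 (SE 0.52, adjusted p = 0.0469) and Gm11559 fell by 2.74 (SE 0.37, adjusted p = 0.0239). Sham signals of Sprr1b (3.67), S100a9 (3.80), Oasl2 (2.64) and 2610528A11Rik (3.52) lay below the array medians. So did the DNCB+HY209 signals of Krt77 (3.48), Cyp2e1 (3.75), Sema3d (3.00), Krtap4-1 (3.19) and Gm11559 (2.46).

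Of 30 lists 10 passed at the preset correlation, 0 with an estimated correlation and 0 with fry. In simulated data with nothing shifted, run for DNCB+HY209 against DNCB only and adjusted over its lists alone, the preset test passed a median of 11.5 lists. Of 21 type I interferon genes 2 rose, Oasl2 and Rtp4 (13 when adjusted over the list alone), with a camera adjusted p = 2.34e-07 (adjusted p = 0.686 with an estimated correlation). Of 15 interferon gamma genes 1 rose, Iigp1 (10 when adjusted over the list alone), with a camera adjusted p = 6.51e-07 (adjusted p = 0.686 with an estimated correlation). In the keratinocyte alarm list 4 of 29 genes rose, Krt6b, Krt16, Sprr1b and the kallikrein gene Klk13, the last named after its value of 4.60 was seen (17 rose when adjusted over the list alone; camera adjusted p = 1.6e-06, adjusted p = 0.766 with an estimated correlation). Cell cycle genes were higher as a list (camera adjusted p = 5.23e-05, adjusted p = 0.766 with an estimated correlation; 0.124 without sham array 2), with log2 differences of 1.52 (SE 0.42, adjusted p = 0.146) for Rrm2 and 1.06 (SE 0.23, adjusted p = 0.0971) for the replication gene Gins1. Oxidative phosphorylation was higher (camera adjusted p = 0.000471, adjusted p = 0.766 with an estimated correlation), with 0.64 (SE 0.16) for Cox5b, whose 5 probe sets ran from 0.24 to 0.80, and 0.68 (SE 0.19) for Ndufv1, neither past the threshold.

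Skeletal muscle genes were higher as a list, with Myh2 (4.66, SE 0.48) the 1 gene of 25 that rose, named for that reason (4 rose when adjusted over the list alone). Its camera adjusted p was 0.00841 (adjusted p = 0.806 with an estimated correlation), 0.857 without sham array 1, with the list mean below that of other genes, and 0.0527 without DNCB+HY209 array 1. Endothelial genes had a camera adjusted p = 0.0313 (adjusted p = 0.766 with an estimated correlation), with 0.102 without sham array 1 and 0.0562 without DNCB+HY209 array 2. Hair follicle genes were lower, with 0 of 32 past the threshold by limma (5 fell when adjusted over the list alone; camera adjusted p = 3.38e-10, adjusted p = 0.766 with an estimated correlation), and Krtap3-1 and Krtap14 differed by -1.90 (adjusted p = 0.0671) and -4.10 (adjusted p = 0.102). The adipocyte list was lower (camera adjusted p = 0.022, adjusted p = 0.766 with an estimated correlation; 0.0610 without sham array 1), as was the immediate early list (camera adjusted p = 0.0229, adjusted p = 0.806 with an estimated correlation; 0.942 without sham array 2 and 0.408 without DNCB+HY209 array 1). Fibroblast and matrix genes did not stand apart (mean 0.18, median 0.055 and camera direction lower, adjusted p = 0.485).

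Of the other genes named by the rule none passed. Krt6a differed by 3.21 (SE 0.63, adjusted p = 0.0671), Flg by 3.65 (SE 1.25, adjusted p = 0.202), Tslp by 1.99 (SE 0.68, adjusted p = 0.202), Il33 by 0.97 (SE 0.58, adjusted p = 0.358) and Il1b by 0.58 (SE 0.34, adjusted p = 0.353). Tnf differed by -0.52, Nlrp3 by 0.15, P2rx7 by -0.35, Lor by -0.60 and Cd4 by -0.39.

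Limma called 50 genes, of which 33 rose and 17 fell, and the median log2 difference of all genes was 0.20. Of these, 49 were also called in DNCB against sham in the same direction (33 higher and 16 lower). The sham arrays enter both comparisons and were too few to split, and simulated data with no HY209 effect gave a median of 597.5 such genes (5% and 95% limits 16.85 and 3763). Those simulations called a median of 787 genes in DNCB against sham, where the data gave 227, so that median is not a like-for-like baseline. The covariance of the differences was 0.367, against 0.0479 in simulations with no effect at all, and their correlation across genes, which are not independent replicates, was 0.930 against 0.635. Krt6b, Krt16, Stfa3 and Sema3d kept their call without each array in turn. The count was 9 without sham array 1, sham array 2 or DNCB+HY209 array 2, 12 without DNCB+HY209 array 3, 18 without DNCB array 1, 32 without DNCB array 3 and 287 without DNCB+HY209 array 1, and it was 8 with the spike-in level as a covariate. It was 97 after quantile normalization, 24 with the mean of a gene's probe sets, 16 with only the groups compared in the fit, 8 without the pair of arrays of extreme spike-in level and 9 with the skeletal muscle level as a covariate. It was 12 with the replicate number as a block, 10 against a change of 1.5-fold and 744 with array weights, whose estimate did not converge.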

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

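All tests of explanations in this part were chosen after the results were seen, except the counts over other splits of the arrays. Probe sets that the annotation does not pair with a single symbol stood outside the comparisons of genes. Tested with all other probe sets, 25 of them passed in DNCB against sham (19 higher and 6 lower) and 10 in DNCB+HY209 against sham (9 higher and 1 lower), which is why they are given here. The lowest p among them in DNCB against sham was that of a probe set shared by several symbols, with a log2 difference of 6.05 (SE 0.23).

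The first pattern was the size of the DNCB response. Over the 227 called genes, a median 0.854 of the log2 difference was kept with the spike-in level as a covariate (quartiles 0.750 and 0.921), while the count fell to 16. These genes were called in the fit without the covariate, which favours genes that vary little within groups. The slope of the covariate rests on that same variation, so the fraction kept cannot decide whether the amount of labelled RNA was the cause. The median absolute difference went from 1.97 to 1.61 with a median SE of 0.33 before and after, and the count was 72 with the covariate's differences alone and 192 with its SE and degrees of freedom alone, so both lowered it and the smaller differences lowered it more. A median of 0.990 was kept after quantile normalization (quartiles 0.921 and 1.03), which argues against scaling. The 0.998 kept with the Gapdh 3' to 5' covariate was fixed beforehand, because its group means differed by -0.013 (SE 0.64) and left nothing to remove. With such close means a linear effect of that ratio could add little to the differences. What stays open is the amount of labelled RNA, RNA quality other than a linear effect of the Gapdh ratio, and how many of the 227 genes respond to DNCB. The last is the biological explanation that the design names, and a part of each difference may follow the spike-in level.

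The second pattern was the lower matrix, vascular and myeloid lists with HY209. The groups differed by -0.017 (SE 0.58) in spike-in level, so a linear effect of that level could add little to the differences. For the same reason the median of 1.01 of the mean differences of the 11 lower lists kept with that covariate was fixed beforehand. Other effects of the amount of labelled RNA stay open. Genes of a list varying together between arrays remain a candidate explanation beside an effect of HY209. With an estimated correlation 0 lists passed, but this held in both comparisons with sham too, so that test cannot decide. In 5 of 100 simulated data sets with nothing shifted at least as many lists passed at the preset correlation. Simulated p-values were adjusted over the lists of 1 comparison and the real ones over 3 comparisons together, so these counts are not like-for-like. The 6 arrays make 10 splits, too few for a share under 0.05: the real split shifted 17 lists and the highest other split 15, and the real split called 0 genes and the highest other 5. The split with the largest difference in spike-in level, -1.08, had 3333 genes at an unadjusted p under 0.05, against 161 in the real split, which points to a structure of the samples that follows the spike-in level.

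The third pattern was the spread of the hair follicle list within groups, with sham array 1 at 8.95 against 6.36 and DNCB+HY209 array 1 at 7.65 against 5.54 and 5.61. Deviations from the group means correlated with those of the melanocyte list over the 8 arrays (Pearson r = 0.983, exact permutation p = 0.0139, the smallest that 72 permutations can give, adjusted p = 0.0417 over 3 relations; rho = 1 with exact permutation p = 0.0139, adjusted p = 0.0417; r = 0.971 without DNCB+HY209 array 1 and sham array 1), in line with the hair cycle phase of the animals as a candidate explanation, though a different number of follicles in the sample would give the same, and no biological group of the design was tested. With the skeletal muscle list r was -0.772 (exact permutation p = 0.0556, adjusted p = 0.0833; rho = -0.476, exact permutation p = 0.278, adjusted p = 0.417) and -0.0779 without sham array 1 and DNCB array 3, so that relation rests on those arrays. With the spike-in level r was 0.297 (exact permutation p = 0.403, adjusted p = 0.403; rho = 0.31, exact permutation p = 0.486, adjusted p = 0.486; r = 0.874 without DNCB array 2 and sham array 2). Neither the share of muscle nor the amount of labelled RNA is excluded by these values, because 8 arrays leave wide intervals.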

How the results depend on the processing

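The covariates and the fit without a pair of arrays were chosen after the data were examined, and the cause of each move was not tested unless stated. For DNCB against sham the main count of 227 genes became 35 with the replicate block, 25 against a 1.5-fold change (a stricter hypothesis), 16 with the spike-in covariate, 452 with the Gapdh covariate, 7 without the 2 arrays of extreme spike-in level, and 27 and 32 with hair and muscle levels as covariates; leaving out single arrays gave 15 to 352. For DNCB+HY209 against DNCB all alternatives run gave 0 genes, those without single arrays (0 to 0) and the replicate block (0) included. For DNCB+HY209 against sham the 50 genes became 97 after quantile normalization, 24 with the mean of probe sets, 744 with array weights, 16 with only the 2 groups compared, 12 with the replicate block, 10 against a 1.5-fold change, 8 with the spike-in covariate, 8 without the 2 arrays of extreme spike-in level and 9 with the muscle covariate; single arrays gave 9 to 287. The array weights did not converge, and DNCB+HY209 array 2 had a weight of 13.01, so 744 is unreliable. Lists passing became 0 with an estimated correlation and 0 with fry in each comparison; those for DNCB against sham became 20 with no filter, and those for DNCB+HY209 against DNCB 11 without the 2 arrays of extreme spike-in level. Single arrays gave 11 to 15, 10 to 16 and 9 to 11 lists in the 3 comparisons, and the replicate block 16, 17 and 11. The share with the opposite sign was 58.1% and 55.5% where DNCB array 1 or 3 stood alone for DNCB on genes chosen without it (31 genes for array 1). It was 91.4% with the replicate block and 48.3% to 94.5% without single arrays, each on the genes called in that fit. The fraction remaining was 0.884 with the block and 0.678 to 1.01 without single arrays. Deviations of arrays with the same number correlated at -0.603 to 0.276 over 7 pairs, and those of arrays with different numbers at -0.658 to 0.611. Deviations from the mean of 2 or 3 arrays are tied to each other, so these values cannot tell whether the numbers pair the samples. Lists that turned, as mean minus that of other genes: cell cycle in DNCB against sham (-0.10 without sham array 2, -0.19 without the 2 extreme arrays; without single arrays -0.10 to 0.66), melanocyte (0.42 with the hair covariate), skeletal muscle in DNCB against sham (-0.23 without sham array 1, -0.36 with the hair covariate, and 0.23 with a camera direction below other genes without DNCB array 1; single arrays to 1.65), hair follicle (-0.019 without DNCB+HY209 array 1, to 1.31), sebaceous (0.028, likewise below by camera, without DNCB array 2, to 0.40) and skeletal muscle (-0.32 without DNCB array 3, to 0.69, and -0.16 with the Gapdh covariate) in DNCB+HY209 against DNCB, and skeletal muscle (-0.014 without sham array 1, to 1.86) and immediate early genes (-0.018, above by camera, without the 2 extreme arrays) in DNCB+HY209 against sham. Single genes that changed sign, none of them called in that comparison: Lor in DNCB against sham (2.18 without sham array 1, and -0.18 after quantile normalization, -0.16 with the mean of probe sets, -0.31 with the replicate block, -1.98 with the spike-in covariate, -2.14, -0.35 and -0.58 without sham array 2, DNCB array 1 and DNCB array 2), Nlrp3 (0.0078 without DNCB array 1); in DNCB+HY209 against DNCB Tslp (0.18), P2rx7 (-0.036) and Krt6a (0.038) without DNCB+HY209 array 1 (-1.22, 0.31 and -0.81 without array 3), Flg (0.18, 0.15, 0.20 and 0.23 without DNCB arrays 1 and 2 and DNCB+HY209 arrays 1 and 2, and -1.11 without array 3) and Lor (0.51 and -2.25 without DNCB+HY209 arrays 2 and 3); in DNCB+HY209 against sham P2rx7 (0.071 with the spike-in covariate) and Lor (1.55, -2.76 and 0.53 without sham arrays 1 and 2 and DNCB+HY209 array 2). Over the alternatives other than single arrays, passing lists kept direction and call in 103, 130 and 79 cases in the 3 comparisons and lost the call in 35, 54 and 28; named genes, called or not, kept direction and side of the threshold in 116, 145 and 129 cases, and called ones lost the call in 29 and 20 in the comparisons with sham, none being called in the other. A lone sham array is assumed to vary like the other groups. Pseudocounts were not run because the values were already on a log2 scale, and the choice of genes with 2 DNCB arrays gives a share only. Without detection calls, low signals cannot be told from background.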

Other observations

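Gene lists that did not stand apart from the other genes in DNCB against sham held single genes past the threshold by limma, named here after their values were seen. Of 18 genes of the NRF2 response and hapten detoxification, Gsto1 (3.07, SE 0.54) and Mgst2 (2.55, SE 0.52) rose, and Aldh3a1 fell by 1.86 (SE 0.34), with a camera adjusted p = 0.614. Of 11 dendritic and Langerhans cell markers, Fscn1, an actin-bundling protein of mature dendritic cells, rose by 2.11 (SE 0.23; camera adjusted p = 0.0907), with 3 probe sets from 0.52 to 2.11. Of 14 genes of the cAMP and bile acid receptor response, Thbd rose by 3.65 (SE 0.59; camera adjusted p = 0.984), and in DNCB+HY209 against DNCB this list had 0 genes past the threshold by limma, a mean of -0.09 and a camera adjusted p = 0.287. Of 34 cornified envelope genes, Rptn rose by 5.51 (SE 0.96) and Krt77 fell by 5.27 (SE 0.79; camera adjusted p = 0.287), and the second probe set of Rptn differed by -0.34. In DNCB+HY209 against sham, Fscn1 rose by 1.86 (SE 0.23; 0.57 at its lowest probe set) and Krt77 fell by 5.68 (SE 0.79), each alone in its list, with camera adjusted p of 0.265 and 0.908. The 26 epidermal lipid barrier enzymes had a mean of 0.68, with 0 past the threshold (6 rose when adjusted over the list alone; camera adjusted p = 0.0569).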
